A study of Mus musculus with 6 samples.

How the data were processed

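Two-colour Agilent arrays measured total RNA of splenic CD4 T cells from C57BL/6J mice. Per the labels' protocols, several spleens were pooled per sample, males and females were used, and CD4 cells were taken with magnetic beads. The sex of the mice in each pool is not given in the sources used here. The labels call the 6 arrays biological replicates in a balanced block with dye swaps. The dose and duration of VIP are not given in the sources used here.

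Per the file headers, the scanned images were read with Agilent Feature Extraction 9.5.1.1, which gave spot intensity, local background and spot flags per channel. Quality columns were used as 0 or 1 flags. The deposited scanner files also hold a log10 ratio of red over green from processed intensity, background-subtracted and dye-normalized per the file headers. The authors' series table holds log10 ratios of VIP over untreated on the scale of those scanner values, with the sign turned where VIP was in Cy3 (largest difference 4.5e-06). Its column medians were 0 on 5 arrays and -0.00022 on replicate 3. It was used as an alternative.

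Mean signal was corrected with normexp (offset 50, median local background) and normalized by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. No scaling between arrays was applied. The 1639 control spots were left out, as were spots with a non-uniformity or population outlier flag; these made up 13.5% of the spots of replicate 5 and between 0.57% and 4.4% on the other arrays. Spots of one probe were averaged. Of 43379 spots, 26788 were named through their RefSeq accession and 1810 through a synonym, from a RefSeq gene table of assembly GRCm38 used for names only, and 14781 kept the name in the file. Each gene was represented by its brightest probe. Genes well above background in at least 3 arrays in the VIP channel or at least 3 in the untreated channel were tested. Probe positions are those of the files, on mm9.

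Per the labels each array is itself the pair of one replicate. The log2 ratio within an array was therefore fitted with a dye intercept and a VIP effect of opposite sign in both orientations. The fit used lmFit and eBayes, with 4 residual degrees of freedom and 6.48 prior degrees of freedom. In replicate 5 sex-linked transcripts differed between both channels, which argues against RNAs from the same pool of mice. Its ratio may therefore not be a paired one. The adjusted p is Benjamini-Hochberg's over all genes tested. The p-values measure the spread between these 6 arrays. The 39 gene lists were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, computed on moderated statistics because some spots had no value. The estimated correlation, fry and rank tests used the 18618 genes with values on all 6 arrays. For some lists that lost their call with the estimated correlation, that correlation was below 0.01, as for cholesterol (-0.013). For those lists a higher correlation cannot account for the loss. The cAMP list, with an estimated correlation of -0.0026, went from a camera p of 9.2e-20 to 0.00063. The p-value of that test was thus larger there without more correlation. Lists also had an exact two-sided sign-flip permutation test of their array medians over 64 sign patterns.

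Genes were named by a rule fixed beforehand. It took the 12 largest rises and 12 largest falls among called genes with a gene symbol and the same sign on all 6 arrays. It also took at most the 4 members with the smallest p of each list described, and Vipr1, Vipr2, Vip, Cd4 and Cd3e. Sex-linked transcripts were one of the lists. Some results for single genes are not reported here.

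Files name 3 slides of 2 arrays each, with 1 array of each orientation. On each slide the array with VIP in Cy5 was at position 2 and the array with VIP in Cy3 at position 4. Alternatives varied the background correction, normalization, filter, flags, probe rule, dye term, weights, prior, pairing, threshold and replicates.

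The fit was tested on simulated data with 22890 genes for the comparison of VIP with untreated. Of 50 genes changed by each size, it recovered 34% at a log2 ratio of 0.2 and 100% at 0.4, 0.6 and 1. In that run it also made 14 calls among unchanged genes. With no gene changed it made 2 calls. The simulated noise was normal, independent between genes and equal across arrays. These rates may therefore be better than those in the real data.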

Results

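Splenic CD4 T cells of C57BL/6J mice, activated with the phorbol ester PMA and the calcium ionophore ionomycin, were profiled with and without vasoactive intestinal peptide (VIP), a neuropeptide whose receptors couple to cAMP. Per the labels, each of 6 two-colour arrays compared VIP-treated with untreated RNA of the same biological replicate. For replicate 5, sex-linked transcripts argue against a shared pool of mice, as described below. VIP was in Cy5 on 3 arrays and in Cy3 on 3. Between 56.9% and 99.9% of the spots were well above background, depending on the array and channel. The number of arrays limits the precision.

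The comparison asked which transcripts differ early between activated CD4 T cells with VIP and without it. Of 22890 genes tested, 378 rose and 105 fell with VIP (limma, Benjamini-Hochberg adjusted p under 0.05). The changes were small. The median absolute log2 ratio of the called genes was 0.305, and 1 of the 483 called genes reached an absolute log2 ratio of 1. That gene was Sgip1, an endocytic adaptor, which was 2.13-fold higher (log2 ratio 1.09 ± 0.058, SE, n = 6 arrays, limma adjusted p = 4.2e-05).

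Among the genes named by the rule, the next largest rise was that of Bend4, which was 1.86-fold higher (log2 ratio 0.90 ± 0.055). The chemokine Cxcl10 was 1.82-fold higher (log2 ratio 0.86 ± 0.072). Epas1, the hypoxia-inducible factor HIF-2 alpha, was 1.80-fold higher (log2 ratio 0.85 ± 0.051). Ccr7, the receptor that guides T cells to lymph nodes, was 1.77-fold higher (log2 ratio 0.83 ± 0.082), and Ccr8 was 1.75-fold higher (log2 ratio 0.81 ± 0.062). Fos, Gpat3, Dusp10, Abcb1b, Lrrc8d and Grap2 followed, with log2 ratios between 0.64 and 0.71. The naming rule required these genes to be higher with VIP on 6 of 6 arrays. Their limma adjusted p lay between 4.2e-05 and 0.00080. Of all 378 genes called higher, 266 had the same sign on all 6 arrays.

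The genes that fell changed less, with -0.655 as the lowest log2 ratio of any called gene. The genes below are those named by the rule. Cilp2 had a log2 ratio of -0.59 ± 0.085 (SE, n = 6 arrays, limma adjusted p = 0.0044), and Pdgfb, a growth factor subunit, had -0.53 ± 0.058. The lymphotoxin genes Lta and Ltb, whose products form a tumour necrosis factor family complex, had log2 ratios of -0.51 ± 0.060 and -0.47 ± 0.062. Cflar, which encodes the caspase-8 inhibitor c-FLIP, had -0.45. Ddr1, Slc39a8, Igsf3, Arhgef2, Gdf9, Wdr59 and Cks2 lay between -0.53 and -0.40. Each of these genes was lower with VIP on 6 of 6 arrays, as the naming rule required. Of all 105 genes called lower, 79 had the same sign on all 6 arrays.

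**Figure D1:**
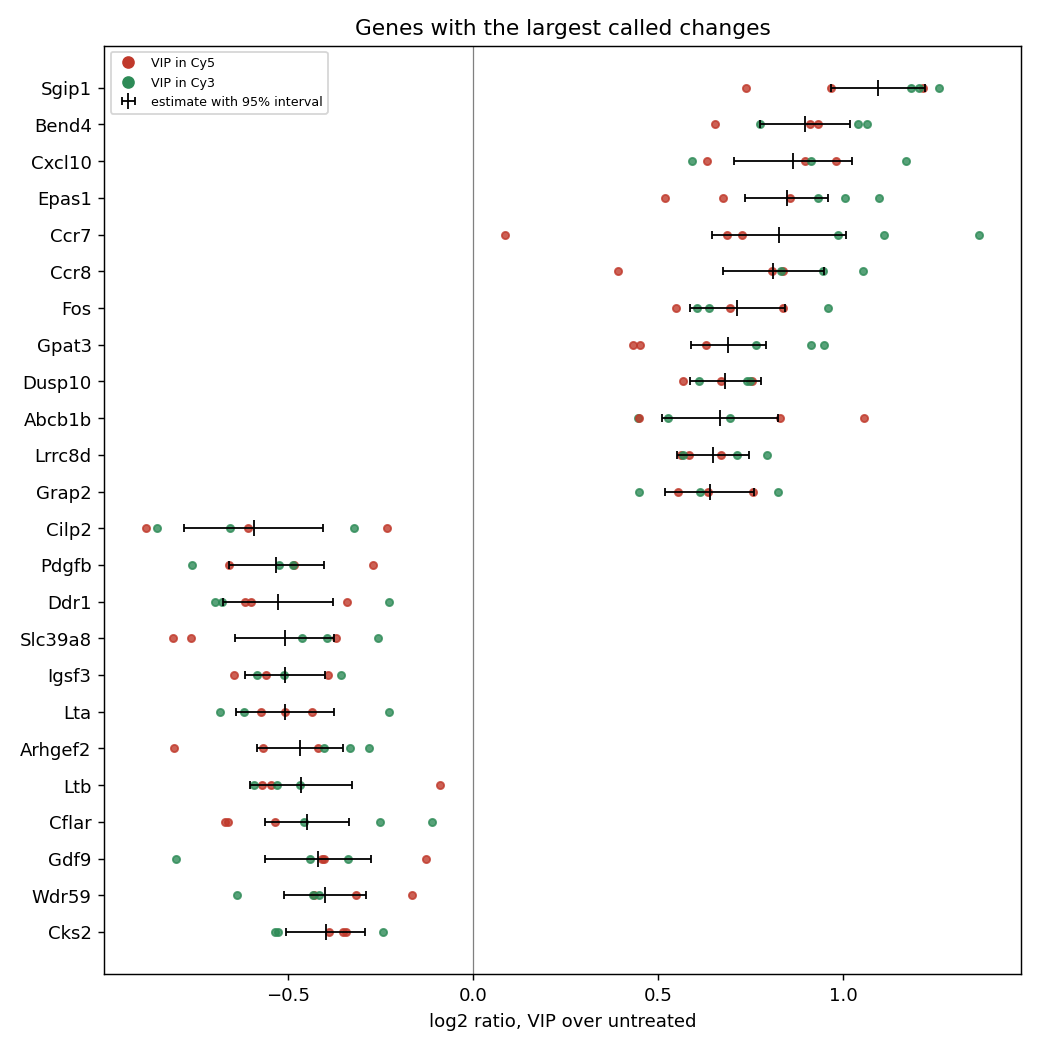
Log2 ratios of VIP over untreated for the 12 largest rises and 12 largest falls among called genes with a gene symbol and the same sign on all 6 arrays. Points are the 6 arrays coloured by the dye of the VIP RNA, and the black mark is the limma estimate with its 95% interval. Of the genes shown, Sgip1 has the highest estimate, 1.09, and Cilp2 the lowest, -0.59.

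The probe of Sgip1 lies on chromosome 4 at 102643625 to 102643684, that of Ccr7 on chromosome 11 at 99005513 to 99005538 and that of Lta on chromosome 17 at 35340275 to 35340334 (mm9). The position of the probes within exons and untranslated regions was not analysed here. The Sgip1 probes differed. The 2 that were tested had log2 ratios of 1.09 and 1.42. A pair of dim probes, with mean log2 intensities of 6.25 and 6.29, had mean log2 ratios of 0.02 and -0.04. Another Sgip1 probe, marked as an outlier on 4 arrays and left out, had -0.07 when its spots were kept. The 3 Grap2 probes ranged from 0.06 to 0.64 and the 4 Arhgef2 probes from -0.47 to -0.12. Of 30 named called genes with more than 1 probe tested, 10 had every probe called in the same direction, 20 had at least 1 probe not called and 3 had a probe in the other direction, with none called in the other direction.

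The counts depended on the arrays and on the background and normalization steps. Without replicate 1 the counts were 185 higher and 30 lower, without replicate 2 they were 248 and 59, and without replicate 3 they were 188 and 39. Without replicate 4 they were 256 and 36, without replicate 5 they were 571 and 250, and without replicate 6 they were 213 and 60. Of the called genes, 78.3% were higher; this share was 89.5% with a normexp offset of 0 (85 higher, 10 lower), 95.8% with median centring (113 and 5) and 100% with Agilent's own log ratios (12 and 0). The VIP orientation also coincided with the position on the slide, so an effect of position on the ratios and the VIP effect cannot be told apart.

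Genes that respond to cAMP, protein kinase A and CREB formed the group with the clearest shift. Of 28 measured members, 13 rose, none fell and 15 did not pass; adjusted over the list alone, 20 rose and 0 fell. Fos, an immediate early transcription factor, had a log2 ratio of 0.71 ± 0.058. Rgs2, a regulator of G protein signalling, had 0.47, Nr4a3, an orphan nuclear receptor, had 0.44, and Fosb had 0.39. The list was higher than other genes (camera adjusted p = 3.6e-18), and this held with an estimated correlation (adjusted p = 0.024). Its median log2 ratio was 0.20 ± 0.043 (mean of the array medians, SD, n = 6 arrays; exact two-sided sign-flip permutation p = 0.03125, the smallest that 6 arrays allow). Within the 3 slides the median was 0.19, 0.18 and 0.22.

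Chemokines and chemokine receptors were higher as a group. Of 23 members, 7 rose, none fell and 16 did not pass; adjusted over the list alone, 9 rose and 0 fell. Ccr8, Cxcl10 and Ccr7 led the list, and Cxcr4 had a log2 ratio of 0.50. The list had a camera adjusted p of 2.2e-07, but adjusted p = 0.18 with an estimated correlation.

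T cell quiescence and Ikaros-family factors were higher, with 3 of 20 members up, 1 down and 16 not passing; adjusted over the list alone, 8 rose and 1 fell. Tcf7, a transcription factor of naive and memory T cells, had a log2 ratio of 0.53 and Klf4, which restrains proliferation, had 0.50. Ikzf3 rose (0.24, with 3 of 4 probes in this direction) and Foxp1, a quiescence factor, fell (-0.36, with its other probe at -0.01 and not called). The camera adjusted p was 7.7e-06, and adjusted p = 0.18 with an estimated correlation. In the T cell identity list, 4 of 20 members rose, among them Ubash3a (log2 ratio 0.32) and Cd28 (0.29), none fell and 16 did not pass; adjusted over the list alone, 4 rose and 0 fell. Its camera adjusted p was 0.0013, and adjusted p = 0.29 with an estimated correlation. Cd4 and Cd3e had log2 ratios of 0.05 and 0.06 and did not pass (limma adjusted p = 0.72 and 0.64). Their probes were dim, with mean log2 intensities of 8.09 and 7.83 in the VIP RNA.

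Of 16 Th2 genes, 3 rose, none fell and 13 did not pass; adjusted over the list alone, 4 rose and 0 fell. Il4ra, a subunit of the interleukin 4 receptor, had a log2 ratio of 0.41 and Il3 had 0.41, beside Ccr8. Il10 had 0.15 and did not pass (limma adjusted p = 0.14). Il4, Il13 and Gata3, given here outside the naming rule, did not pass either. Each had a log2 ratio of 0.01 (limma adjusted p = 0.97, 0.96 and 0.96). The list's camera adjusted p was 7.5e-05, and adjusted p = 0.20 with an estimated correlation. The Th1 and inflammatory cytokine list was not called (camera adjusted p = 0.30): Csf2 was among 3 of 20 members that rose, Lta and Ltb fell, and 15 did not pass. Adjusted over the list alone, 4 rose and 3 fell. Of 14 Th17 genes none rose or fell over all genes and 14 did not pass; adjusted over the list alone, 3 rose and 0 fell. That list's camera adjusted p was 0.017, and adjusted p = 0.29 with an estimated correlation.

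In the G protein signalling list, 4 of 26 members rose, among them Rgs1 (log2 ratio 0.33) and Rgs10 (0.33), none fell and 22 did not pass; adjusted over the list alone, 6 rose and 0 fell. Its camera adjusted p was 0.0035, and adjusted p = 0.34 with an estimated correlation. Of 25 JAK-STAT receptors and SOCS genes, 6 rose, 1 fell and 18 did not pass; adjusted over the list alone, 9 rose and 6 fell. Ifngr2 had a log2 ratio of 0.38 and Il21r had 0.31. The camera adjusted p was 0.033, and adjusted p = 0.39 with an estimated correlation. Of 20 TGF-beta and SMAD genes, 2 rose (Id2, log2 ratio 0.58, and Id1, 0.42), none fell and 18 did not pass, and adjusted over the list alone 2 rose and 0 fell. That list's camera adjusted p was 0.038, and adjusted p = 0.29 with an estimated correlation. Of 28 interferon-stimulated genes, 4 rose, none fell and 24 did not pass, with the same counts of 4 and 0 adjusted over the list alone. The camera adjusted p was 0.0093, and adjusted p = 0.52 with an estimated correlation.

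Lists that were lower comprised cholesterol and lipid synthesis and the S to M phase of the cell cycle. In the cholesterol list 1 of 23 members fell, Srebf2, a regulator of cholesterol synthesis (log2 ratio -0.22), none rose and 22 did not pass; adjusted over the list alone, 3 fell and 1 rose. Of 4 Srebf2 probes, 1 was in this direction, and they ranged from -0.22 to 0.05. Its median lay below 0 on 6 of 6 arrays, with a camera adjusted p of 0.00019, and adjusted p = 0.29 with an estimated correlation. In the cell cycle list Mcm4, a subunit of the replicative helicase, fell (-0.24), none rose and 26 of 27 did not pass; adjusted over the list alone, 2 fell and 0 rose. Of 2 Mcm4 probes, 1 was in this direction, and they ranged from -0.24 to 0.08. That list's camera adjusted p was 0.0496, and adjusted p = 0.63 with an estimated correlation. Its call was lost in 20 of 24 alternative settings, and its median was above 0 with median centring. Ribosomal protein genes were called higher with none of 32 members passing, over all genes or adjusted over the list alone, at a camera adjusted p of 0.0093, and adjusted p = 0.49 with an estimated correlation. Their array medians before removal of the dye effect were 0.63, 0.75 and 0.86 where VIP was in Cy5 and -0.56, -0.37 and -0.34 where it was in Cy3 (exact two-sided sign-flip permutation p = 0.5625, n = 6 arrays). Of the 32 members, 12 had a saturated spot on at least 1 array.

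Marker lists of B cells, monocytes and plasma cells were called higher at the preset correlation, and these calls were lost with an estimated one. The estimated correlations were -0.016 for B cells, 0.029 for monocytes and -0.025 for plasma cells. Those of B and plasma cells lie below the preset 0.01, so a higher correlation cannot account for their lost calls. Camera with ranks still called all of them higher (adjusted p = 0.011, 0.011 and 0.0497). Fry called B and plasma cells higher (adjusted p = 0.017 and 0.045) but not monocytes (0.20). None of 18 B cell markers passed over all genes or adjusted over the list alone, and the list's median log2 ratio was 0.06 (camera adjusted p = 0.013; adjusted p = 0.29 with an estimated correlation). Among 19 monocyte and macrophage markers Cd14 rose (log2 ratio 0.57, n = 5 arrays), none fell and 18 did not pass, and adjusted over the list alone 1 rose and 0 fell. That list's camera adjusted p was 0.0093, and adjusted p = 0.29 with an estimated correlation. None of 8 plasma cell markers passed over all genes or adjusted over the list alone (camera adjusted p = 0.049; adjusted p = 0.29 with an estimated correlation). Markers of dendritic cells, NK cells, CD8 T cells, neutrophils, erythroid cells and platelets were not called, with camera adjusted p of 0.081, 0.46, 0.46, 0.58, 0.30 and 0.37. Of these, the dendritic cell list was called higher by fry (adjusted p = 0.017), with 1 of 14 members up, Ccr7, and a dye-adjusted median above 0 on 6 of 6 arrays.

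Of the called lists, the cAMP list kept its call in all 24 alternative settings. The calls of plasma cell markers, JAK-STAT genes, TGF-beta genes and ribosomal proteins were lost in 15, 11, 9 and 9 of them, and those of interferon-stimulated genes, Th17 genes and B cell markers in 7, 7 and 4. Those of the G protein, cholesterol and monocyte lists were lost in 3 each, and those of the chemokine, quiescence, T cell identity and Th2 lists in 1 each, the estimated correlation. Without replicate 1 the camera adjusted p was 0.067 for Th17 genes, 0.174 for interferon-stimulated genes, 0.065 for JAK-STAT genes, 0.077 for TGF-beta genes, 0.174 for plasma cell markers, 0.123 for monocyte markers and 0.271 for the cell cycle. Without replicate 2 it was 0.157 for the cell cycle. Without replicate 3 it was 0.095 for Th17 genes, 0.081 for interferon-stimulated genes, 0.136 for JAK-STAT genes, 0.094 for TGF-beta genes, 0.086 for ribosomal proteins and the cell cycle and 0.060 for plasma cell markers. Without replicate 4 it was 0.104 for the cell cycle and 0.073 for plasma cell markers, and without replicate 5 it was 0.084 for B cell markers and 0.086 for plasma cell markers. Without replicate 6 it was 0.0502 for JAK-STAT genes, 0.222 for TGF-beta genes, 0.203 for ribosomal proteins and 0.138 for plasma cell markers. The exact sign-flip permutation p was 0.03125 for the quiescence, T cell identity and cholesterol lists. It was 0.0625 for the chemokine, G protein, monocyte and TGF-beta lists and 0.094 for the Th2, Th17 and B cell lists. It was 0.125 for JAK-STAT genes, 0.1875 for plasma cell markers and the cell cycle and 0.4375 for interferon-stimulated genes. These array medians still held the dye effect.

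**Figure D2:**
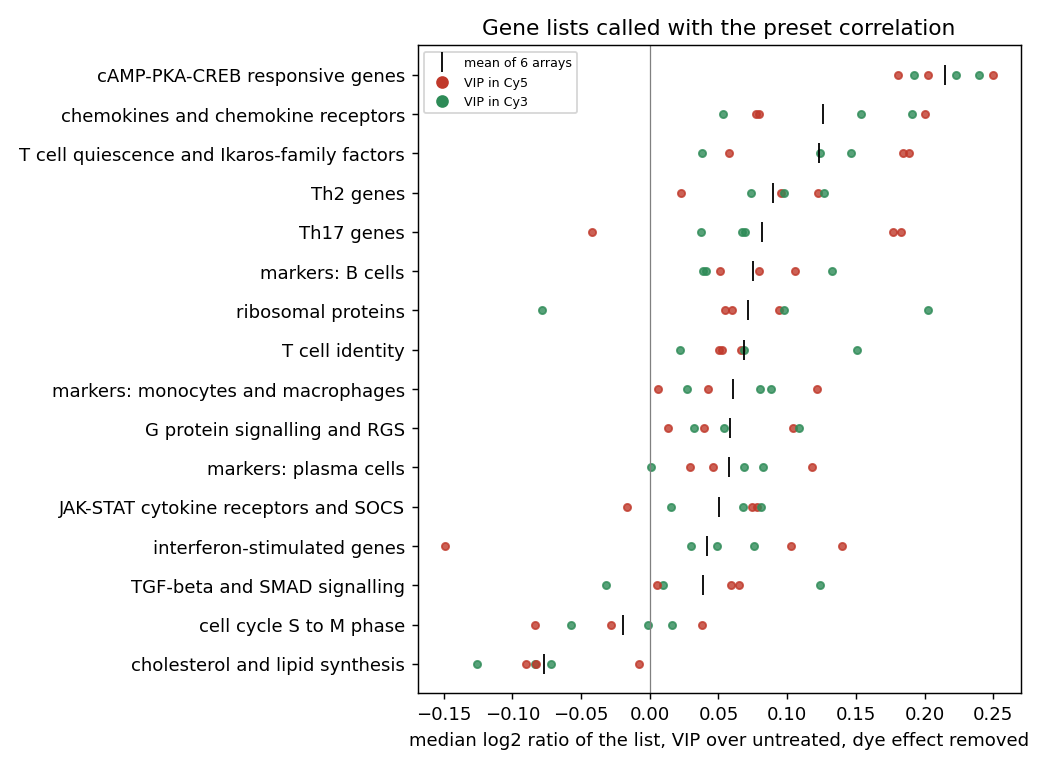
Median log2 ratio of VIP over untreated for the members of each called list, after removal of the fitted dye effect. Points are the 6 arrays coloured by the dye of the VIP RNA and the black mark is their mean; the cAMP list lies above 0 on all 6 arrays.

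Several lists held called members without being called themselves. Of 22 MAPK feedback and AP-1 genes, 4 rose (Dusp10, Fos, Fosb and Dusp1, the last measured on 3 arrays), none fell and 18 did not pass; adjusted over the list alone, 5 rose and 2 fell (camera adjusted p = 0.27). Of 20 homing and adhesion genes, 4 rose (Ccr7, Selplg, Itga6 and S1pr1), none fell and 16 did not pass; adjusted over the list alone, 4 rose and 1 fell (camera adjusted p = 0.21). In the costimulation list Cd28 rose (log2 ratio 0.29), Slamf6 (-0.34) and Tnfsf14 (-0.22) fell and 14 of 17 did not pass; adjusted over the list alone, 2 rose and 3 fell (camera adjusted p = 0.89). In the NF-kB list Rel rose (0.26), Cflar fell and 22 of 24 did not pass; adjusted over the list alone, 4 rose and 2 fell (camera adjusted p = 0.45). The MAPK, homing and NF-kB lists were called higher with median centring, the MAPK and NF-kB lists were also called higher by fry, which does not compare a list with other genes, and the MAPK list also without the pairing of channels. The median log2 ratio of the MAPK list was -0.0012, although its test pointed up. The Th1, glycolysis, ribosome biogenesis and housekeeping lists were also called higher with median centring, and the apoptosis list was called lower by fry (adjusted p = 0.021).

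The receptor Vipr1 had a log2 ratio of 0.20 ± 0.056 (SE, n = 6 arrays) and did not pass (limma adjusted p = 0.12). Vip was well above background on 3 of 6 arrays in the VIP channel and 2 in the untreated channel, so its log2 ratio of -0.03 (limma adjusted p = 0.86) was measured near background. Of the 6 measured genes of the VIP and PACAP receptor list none passed; adjusted over the list alone, 2 rose (Dpp4, log2 ratio 0.17, and Vipr1) and 0 fell. The list was not called (camera adjusted p = 0.27). Vipr2 was not well above background in either channel on enough arrays to be tested. In the TCR and NFAT activation list 2 of 23 members rose (Nr4a3 and Nr4a1), none fell and 21 did not pass; adjusted over the list alone, 4 rose and 4 fell. The list was not called (camera adjusted p = 0.86), and it was called higher with median centring. Egr2, an early growth response factor, had a log2 ratio of -0.29 and did not pass (limma adjusted p = 0.0504). Nr4a1 was close to the upper end of the scanner's range, with a saturated spot on 1 array, and its ratio had a dye effect of 0.87. Its direction of VIP over untreated was positive on 3 of 6 arrays before that dye effect was removed.

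Sex-linked transcripts differed between both channels of replicate 5. In that replicate Ddx3y was 17.4-fold and Eif2s3y 18.6-fold higher in the VIP RNA, and Xist was 9.64-fold higher in the untreated RNA. On the other 5 arrays the log2 ratio of Ddx3y lay between -0.10 and 0.39 and that of Xist between -0.34 and 0.46. In replicates 3 and 4 Xist was low in both channels, with log2 intensities of 7.09 and 6.63 in the VIP and untreated RNA of replicate 3 and 6.09 and 5.93 in those of replicate 4. Ddx3y was low in both channels of replicate 6, with 7.20 and 7.30, and in the untreated RNA of replicate 5, with 7.45. The sex-linked list was not called (camera adjusted p = 0.42).

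**Figure D3:**
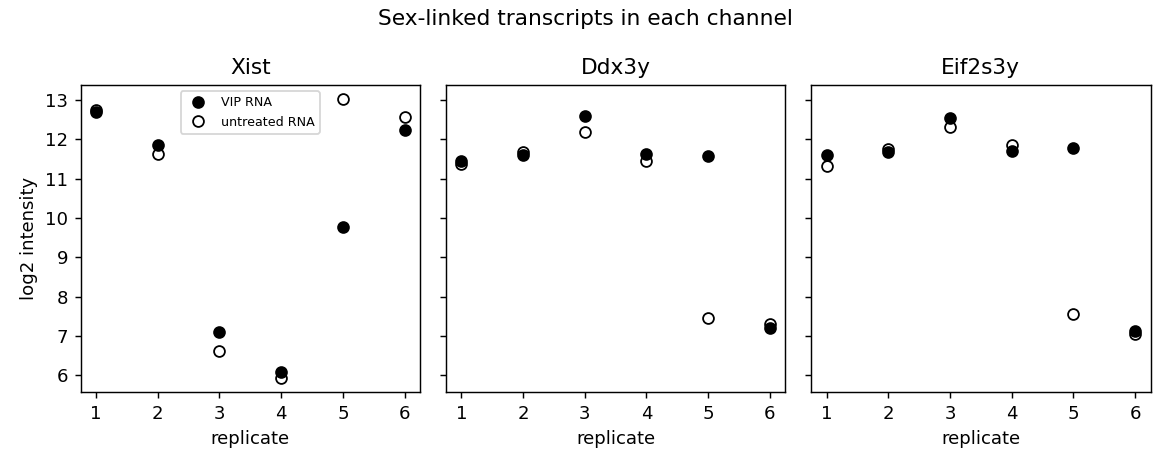
Log2 intensity of Xist, Ddx3y and Eif2s3y in the VIP RNA (filled) and the untreated RNA (open) of each replicate. The channels of replicate 5 differ, with Xist at 9.76 in the VIP RNA and 13.03 in the untreated RNA.

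Dye effects were widespread: 1555 genes (6.79% of those tested) had a limma dye coefficient past the threshold. Among them were 61 of the 483 genes called for VIP (12.6%), a higher share. Correlations across genes of the red over green ratio averaged 0.403 for the 6 array pairs of the same orientation and 0.152 for the 9 pairs of opposite orientation. Taken as VIP over untreated, the correlations of those 9 pairs were negative, from -0.291 to -0.0865. Genes are not independent replicates.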

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

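The test of T cell markers and the dye adjustment of X-linked genes were chosen after values were seen; the other tests of replicate 5 and of the splits were written before their results were seen. Of 87 named genes and 39 lists compared over the 6 arrays, 1 gene and 2 lists passed a test for an outlying array on dye-adjusted values. Chance would give about 1 in 20 for independent values. The dye effect was fitted on the same arrays, so the values are not independent and an outlying array can be missed. Ddx3y and Xist did not pass, although their log2 ratios in replicate 5 were 4.12 and -3.27 before that adjustment.

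Eif2s3y stood apart in replicate 5, with a dye-adjusted log2 ratio of 3.41. Before that adjustment Ddx3y was 17.4-fold and Eif2s3y 18.6-fold higher in its VIP RNA, and Xist 9.64-fold higher in its untreated RNA. These values argue against RNAs from the same pool of mice in replicate 5. If both channels of replicate 5 had been exchanged, genes called without it would be reversed there; their median signed log2 ratio in replicate 5 was 0.129 and 70.5% kept their sign, which argues against an exchange. On the other 5 arrays, each left out in turn, that median lay between 0.298 and 0.427, but for genes with a median absolute log2 ratio of 0.367 to 0.398 in the arrays kept, against 0.272 for those of replicate 5, so whether the RNAs of replicate 5 differed in treatment as fully as the others stays open. Pools of a different sex mix may account for the transcripts: X-linked genes that escape inactivation had a median log2 ratio of -0.191 in replicate 5 against -0.090 at the lowest of the other arrays, values whose sign followed the dye on all 6 arrays, and with the dye effect of the other arrays removed -0.400 against -0.040, with 3 of 4 genes measured there and Ddx3x at 0.03. Beyond the sex of the mice, no biological explanation was tested.

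B cell and monocyte marker lists were called higher with VIP, with adjusted p = 0.29 for each with an estimated correlation. A lower share of T cells in the VIP RNA would lower the T cell identity list, whose array medians averaged 0.079 ± 0.035 (SD, n = 6 arrays), above 0 on 6 of 6 arrays. More B cells in the VIP RNA stays open. The cells were selected with anti-CD4 beads, but how many B cells remained was not measured. The mean log2 intensity in the VIP RNA was 14.70 for Ighm and 14.25 for Cd74. Over the 18 B cell markers tested it averaged 9.91. Intensities of different probes do not measure cell shares. A change in expression of these markers may also contribute and was not tested.

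The T cell identity list stood apart in replicate 6, with a dye-adjusted median of 0.15, and so did the circadian clock list, with 0.096. Replicate 6 was also the brightest array, with a median red signal of 737.0 and a median green signal of 294.3. Replicate 5 had flags on 13.5% of its spots and 64 saturated red spots, against at most 4 on the other arrays.

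Of the 10 ways to split the 6 arrays into 3 against 3, the real orientation called 483 genes and the highest other split 2; 1 split, the real one, reached that count. For lists the real orientation called 16 and the highest other split 8, and again 1 split reached the real count. With 10 splits no share under 0.05 can be had. The other splits are not free of a VIP effect either. Any such effect enters their contrast in part and adds to their residual spread, which lowers their gene counts.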

How the results depend on the processing

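The slide blocks were chosen after seeing the data. All 483 called genes kept their direction with Agilent's processed log ratios and with the authors' table. Of them, 479 had an unadjusted limma p under 0.05. These genes were chosen on the same arrays, so this carries little added information. In both settings 12 genes were called higher and 0 lower. The prior degrees of freedom fell from 6.48 to 2.24 and the median residual SD was 0.194. The authors' table holds the scanner's ratios, so both settings are in effect the same alternative. A normexp offset of 0 gave 85 higher and 10 lower. Median centring gave 113 and 5, no dye term 189 and 38, and array weights 208 lower. Without the pairing of channels within arrays (no replicate block), 1 gene was higher and 0 lower, and 128 of the 483 had an unadjusted p under 0.05. In this balanced design the estimates stay almost the same without pairing, with a median size ratio of 1. That 483 of 483 kept their direction therefore carries no added information. An adjusted p under 0.01 gave 182 and 33, one under 0.10 gave 211 lower, and a log2 ratio of at least 0.5 gave 51 and 7. Dye effects numbered 70 with an offset of 0, 16 with Agilent's ratios and the authors' table, and 14420 with median centring. Higher lists numbered 9 with Agilent's ratios and the authors' table, 8 with the strict filter and 1 with an estimated correlation. Lower lists numbered 0 with median centring, an estimated correlation and ranks, and 1 without background subtraction, with an offset of 0, Agilent's ratios, the authors' table, scaling, Aquantile, the strict filter, outlier spots kept, the mean of probes, no dye term, no pairing and the slide as a block. Leaving out each replicate gave 185 to 571 genes higher, 30 to 250 lower, 281 to 2502 with a dye effect, 8 to 14 higher lists and 1 to 2 lower. The slide as a block gave 356 and 104 genes. Sgip1 had -0.068 with outlier spots kept, because a brighter probe marked as an outlier on 4 arrays then stood for it. The TCR and NFAT list reversed to 0.083 with median centring. Other causes were not tested. The cAMP list was called in all 24 settings, with medians from 0.18 to 0.32. A slide or scan block was planned only for a batch with more than 1 array of each orientation, which no slide or scan had, so the planned form was not run; scans grouped the arrays as slides did, and the slide was blocked as an added alternative. Signal over background left Vipr2 untested; of 22890 genes, 14323 were well above background in both channels on all arrays, and among these 372 rose and 104 fell.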

Other observations

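The Gimap test was chosen after its values were seen, and the test of its neighbours was written before its result was seen. Gimap genes encode GTPases of lymphocytes. All 7 measured members rose with VIP, with log2 ratios from 0.26 for Gimap9 to 0.45 for Gimap6. Among 535 families of genes with a shared symbol stem, 2 were higher and 0 lower. The Gimap family had a camera adjusted p of 1.2e-11, but adjusted p = 0.85 with an estimated correlation, and it was noticed before the families were compared, so a shift of the family beyond others remains a hypothesis. The genes lie together on chromosome 6, between 48627839 and 48715093 (mm9). A change of the whole neighbourhood would move the other genes there: the median log2 ratio of 23 genes within 500 kb was 0.017 ± 0.016 (SE across genes), against 0.29 for the family, which argues against it. Cross-hybridisation between family members may contribute and was not tested.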
